A study of Homo sapiens with 16 samples.

How the data were processed

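The 16 libraries were human RNA sequencing libraries made with a kit that primes complementary DNA from polyadenylated RNA of few cells. According to the submitters, reads were aligned with STAR 2.7.10b, assigned to genes with Subread 2.0.6 and scaled with DESeq2 1.30.1, on the GRCh38.p13 (hg38) genome. The strand setting, the annotation release and the handling of reads that map to several places or to overlapping genes were not given in the sources used here. Values of antisense transcripts that overlap another gene therefore carry that uncertainty. Reads from a lentiviral copy of a factor and from the native gene were counted together, so the level of a factor is the sum of both.

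The deposited table held raw read counts for 61217 genes, of which 20895 carried an Ensembl identifier in place of a symbol. A second table held normalized signal values, which the authors deposited as DESeq2-scaled counts and which equalled the raw counts divided by 1 size factor per library, between 0.524 and 2.61. The raw counts were used for every result, and the normalized values only for 1 alternative fit.

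CPM values are counts divided by the library total on the usual CPM scale, with M for reads on the same scale, and are given as mean ± SD over the libraries of a group. Differential expression was tested with edgeR 4.0.16 (quasi-likelihood fit, robust estimation, TMM scaling, filterByExpr) in R 4.3.3. The 12 iEC libraries were fitted together with 1 mean per group, which gave 22574 tested genes and a biological coefficient of variation of 0.508. The mean of the 3 combinations was tested against control as a contrast of this fit. The 4 iBMEC and 3 control libraries were fitted separately, which gave 24607 tested genes and a coefficient of 0.336. Log2 fold changes are given ± SE. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes tested in that comparison. Each p value measures the spread between these libraries. The labels do not say whether the replicates were separate differentiations or wells of 1 differentiation.

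The 8 comparisons, the 26 gene lists with 373 genes and the rule for naming genes were fixed before the data were examined. The rule named the 9 transduced factors. It named the 8 called genes with the highest and the 8 with the lowest fold change in each comparison with control, and 5 of each in comparisons between combinations and in the mean of the 3 combinations. Such a gene needed a mean log2 CPM of at least 3 and groups whose libraries did not overlap. Chance gives such groups for 10% of genes with 3 libraries against 3, 5.71% with 4 against 3 and 0.91% with 9 against 3. Genes without an approved-style symbol, mitochondrial genes and sex-linked genes used for identity checks were passed over. Some genes that met the rule are not reported here. Up to 4 members of each list were named by the size of their change among those called. Genes that the text names outside this rule are said to have been chosen after their values were seen.

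The gene lists held textbook members. Vessel identity was covered by markers of arterial, venous, capillary, lymphatic and blood-brain barrier endothelium, by pan-endothelial genes and by genes of tip cells and angiogenesis. Other cell types were covered by epithelial, mesenchymal, pluripotency, haematopoietic and neural markers. Signalling and state were covered by lists for the Notch pathway, Wnt and beta-catenin targets, the response to KLF2 and flow, PPARD targets and fatty acid oxidation, TGF-beta targets, BMP targets, interferon response, NF-kB inflammation, p53 targets, the integrated stress and unfolded protein responses, hypoxia and glycolysis, sterol synthesis, the cell cycle, and tight and adherens junctions. The 9 transduced factors stood on none of the 26 lists and are given gene by gene. Some genes stand on more than 1 list, so lists are not independent of each other. Each list with at least 5 tested members was tested against all other genes with camera at a preset correlation of 0.01, and its p was adjusted over the lists of that comparison. The haematopoietic and neural lists had 4 tested members in the iEC fit and were not tested there. A preset correlation takes the genes of a list to vary nearly independently, so each camera call is given with the adjusted p from an estimated correlation where that ended the call. Counts of members that rose or fell are over all genes tested, and are also given "adjusted over the list alone".

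Where every library of a group had 0 counts, the fold is a lower bound against 3 counts over the whole group, which is 0.0118 CPM for the control group and 0.00592 CPM for the iBMEC group. Where a group had 1 to 3 counts in total, the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only. Reads without molecular identifiers are not independent molecules.

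A self-test on independent genes simulated with the depth and spread of these libraries had 21401 for 3 against 3. The edgeR fit recovered 16.3% of genes with a 2-fold and 53.7% of those with a 4-fold change. Of its 69 calls 2 were false. With 4 against 3 and 23311 genes it recovered 30.9% and 62.6%, and 10 of 97 calls were false. DESeq2 made 40 false calls of 119 and 56 of 165, and limma 1 of 70 and 14 of 102. The list test called 2 of 2 changed and 0 of 50 unchanged lists with either correlation, which independent genes cannot rank.

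Differences in treatment run along with the groups. The cells of the 3 combinations were transduced and selected with puromycin, whereas control iECs were exposed to polybrene and doxycycline but neither transduced nor selected. No comparison with control can separate the factors from transduction and selection. The iBMECs received none of these treatments and were cultured for 2 days before lysis in place of 8.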

Results

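The data came from endothelial cells made from WTC-ZO1, a human induced pluripotent stem cell line that carries a tagged tight junction protein. Endothelial cells of arteries, capillaries and veins express different genes, and the series asked what combinations of transcription factors linked to each vessel type do to stem cell-derived endothelial cells (iECs). The cells were transduced with doxycycline-inducible lentiviruses at a multiplicity of infection of 3 to 5. The arterial combination held HEY1 and PRDM16. The capillary combination held LEF1, KLF2, TSC22D1 and FOXP1. The venous combination held PPARD, FLI1 and TSHZ2. Transduced cells were selected with 0.5 µg/mL puromycin for 3 days and then induced with 10 µg/mL doxycycline for 3 days. Control iECs received polybrene and doxycycline only. The last group consisted of iBMECs, cells made from the same line by a protocol intended to give brain microvascular endothelial cells.

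Polyadenylated RNA was sequenced in 3 libraries of each iEC group and 4 iBMEC libraries, 16 in total. Read totals were 121.6, 77.4 and 55 M in the control libraries and 85.7, 82.2 and 94.8 M in the arterial ones. They were 98.3, 124.6 and 100.8 M in the capillary libraries and 74.9, 140.7 and 54 M in the venous ones. The iBMEC libraries held 106, 90.4, 206.4 and 103.8 M reads. Mitochondrial genes took 10.3% ± 1.6 of the counts in control (SD, n = 3), 6.6% ± 0.702 in arterial, 7.97% ± 2.29 in capillary and 9.86% ± 1.75 in venous libraries (n = 3 each). Their share was 6.85% ± 0.118 in iBMECs (n = 4). Replicates of every group differed from each other by more than sampling noise, with chi-square values per degree of freedom of 36.2 to 556 between pairs.

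Arterial replicate 1 stood apart from the other 11 iEC libraries. On the first principal component of log2 CPM, with 25.7% of the variance, it had a score of 224.5, and the others lay between -57.8 and 29.1. When every library was thinned to 50 M reads, it had 16258 genes with at least 10 counts, the fewest of the iEC libraries. Controls had 18077 to 18583 such genes, capillary libraries 17760 to 18363 and venous ones 16983 to 17578. The second component, with 17.7% of the variance, held the controls at 86.7 to 95 and all 9 transduced libraries at -63.4 to 45.4. The third, with 13.5%, held the capillary libraries at -94.3 to -49.6 and the others at -30.8 to 83.7. Arterial replicate 1 also carried 7.35 CPM of LEF1, a factor of the capillary combination, against 0.584 and 0.401 CPM in the other two arterial libraries.

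**Figure D1:**
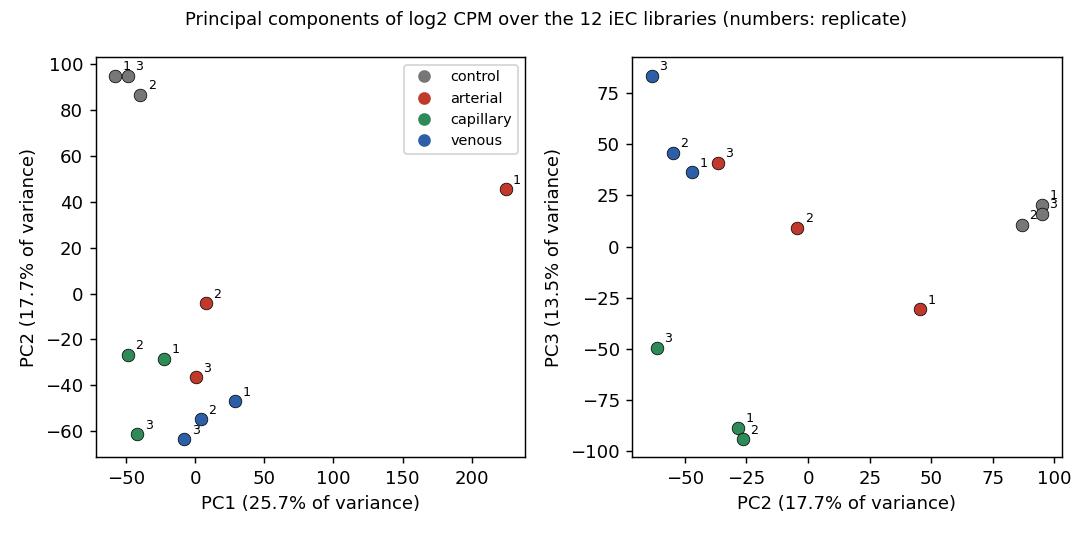
Scores of the 12 iEC libraries on principal components 1 and 2 (left) and 2 and 3 (right) of log2 CPM. Each point is a library with its replicate number, colored by group. Arterial replicate 1 lies at 224.5 on the first component.

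Which of the introduced factors were visible in the reads? PRDM16, LEF1, PPARD and KLF2 were higher in the combination that contained them than in control. PRDM16, a zinc finger regulator that helps maintain arterial endothelial identity, rose by 7.13 ± 1.37 on the log2 scale in the arterial combination, to 3.86 ± 2.62 CPM from 0.0364 ± 0.063 (n = 3 each, adjusted p = 0.0072). Its 3 arterial libraries had 1, 6.16 and 4.43 CPM. LEF1, a nuclear effector of Wnt signalling, rose by 6.58 ± 1.09 in the capillary combination, to 56.1 ± 15 CPM (adjusted p = 0.0033). PPARD, a nuclear receptor for fatty acids, rose by 3.84 ± 0.51 in the venous combination, to 18.8 ± 3.65 from 1.41 ± 0.398 CPM (adjusted p = 0.00027). Each of these 3 kept its call when any single library was left out.

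KLF2, a factor induced by blood flow, was 1.88 ± 0.53 higher in the capillary combination, with 4.19 ± 1.24 against 1.17 ± 0.378 CPM, at an adjusted p of 0.05 that lay just under the threshold. That call was lost without any single control or capillary library, at an adjusted p between 0.057 and 0.17. KLF2 was also 1.84 ± 0.54 higher in the venous combination, which did not contain it (adjusted p = 0.033). There the call was lost without control replicate 1 (0.058), 2 (0.11) or 3 (0.09) and without venous replicate 2 (0.067) or 3 (0.11). The capillary combination did not differ in KLF2 from the other two combinations (0.21, adjusted p = 0.91).

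HEY1, TSC22D1 and TSHZ2 were not detectably higher in their own combination than in control. HEY1, a Notch-responsive repressor, stood at 68.3 ± 12.1 CPM in the arterial combination and 69.8 ± 8.38 in control (0.08 ± 0.23, adjusted p = 0.89). It was 1.0 ± 0.19 higher in the arterial combination than in the other two (adjusted p = 0.025). Against control it fell by 1.03 in the capillary combination (adjusted p = 0.013) and by 0.82 in the venous one (adjusted p = 0.025). The capillary call was lost without control replicate 2 (0.057) or 3 (0.073) or capillary replicate 2 (0.07) or 3 (0.069). The venous call was lost without control replicate 1 (0.055), 2 (0.11) or 3 (0.14) or venous replicate 2 (0.12) or 3 (0.052). TSC22D1 had 298 ± 63.6 CPM in the capillary combination and 230 ± 19.2 in control (0.41 ± 0.19, adjusted p = 0.27), and TSHZ2 had 4.62 ± 0.908 in the venous combination and 3.95 ± 1.33 in control (0.35 ± 0.4, adjusted p = 0.66).

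FOXP1 and FLI1 fell in the combinations that contained them. FOXP1, a forkhead factor of the capillary combination, was at 76.8 ± 11.9 CPM there and 155 ± 5.18 in control, a log2 change of -0.97 ± 0.14 (adjusted p = 0.00075). It changed by -0.97 in the arterial combination (adjusted p = 0.0016) and by -1.07 in the venous one (adjusted p = 0.00031). FLI1, an ETS factor that maintains endothelial genes, was at 97.4 ± 33.3 CPM in the venous combination and 182 ± 26.1 in control, a change of -0.78 ± 0.22 (adjusted p = 0.028). This was lost without control replicate 1 (0.15), 2 (0.053) or 3 (0.1) and without venous replicate 1 (0.1) or 2 (0.13). FLI1 also changed by -0.79 in the arterial combination (adjusted p = 0.042), a call lost without any single library of the comparison (0.073 to 0.2), and was not called in the capillary one (-0.62, adjusted p = 0.12).

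**Figure D2:**
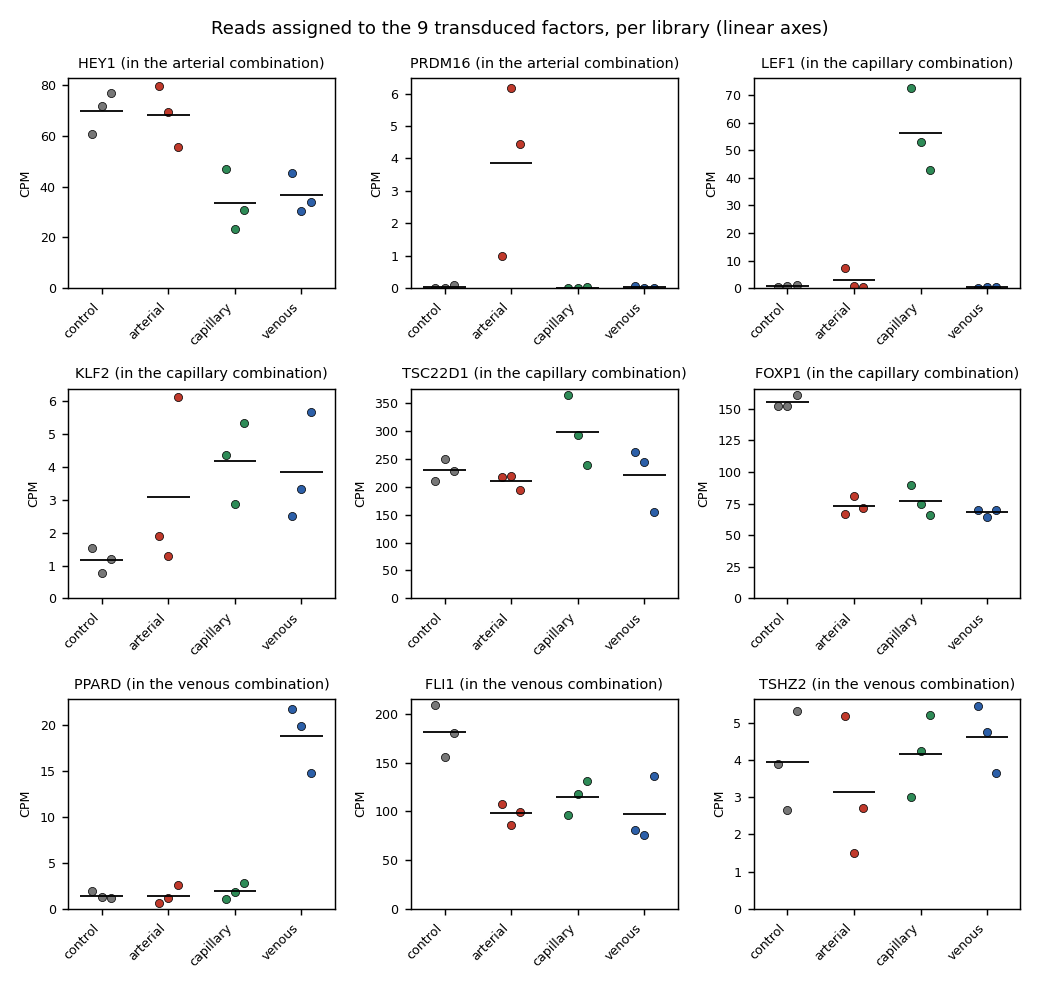
Reads assigned to each of the 9 factors in the 12 iEC libraries, in CPM on linear axes. Points are libraries by group and lines are group means. PRDM16, LEF1 and PPARD were highest in all 3 libraries of the combination that contained them.

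What changed with the arterial combination? SERPINB2, an inhibitor of plasminogen activation, rose 22.4-fold (4.48 ± 0.45, adjusted p = 0.00024), to 92.1 ± 34.9 from 4.44 ± 2.6 CPM (n = 3 each). IL1RL1, the receptor of the cytokine IL-33, rose 15.2-fold to 3380 ± 773 from 240 ± 102 CPM (adjusted p = 0.00024). CXCL8, a chemokine that attracts neutrophils, rose 10.8-fold to 446 ± 86.7 from 44.7 ± 7.9 CPM (adjusted p = 0.00085). NPR3, a clearance receptor for natriuretic peptides, fell 19.1-fold to 7.8 ± 4.89 from 161 ± 16.3 CPM (adjusted p = 0.002). VWF, the clotting protein stored by endothelial cells, fell 8.21-fold to 12.2 ± 0.326 from 108 ± 19.6 CPM (adjusted p = 0.00024).

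The other highest genes were ANOS1 (4.33 ± 0.54), CRABP2 (3.89 ± 0.52), MGARP (3.81), CST1 (3.46 ± 0.63) and TNFSF18 (3.27 ± 0.64), a ligand of the tumor necrosis factor family. Others among the lowest were SLCO2A1 (-3.99 ± 0.76), a prostaglandin transporter, PLCE1-AS1 (-3.94), SULF1 (-2.92 ± 0.61), the protease inhibitor A2M (-2.88 ± 0.34) and DNASE1L3 (-2.7 ± 0.3). CST1 was lost without control replicate 1 (adjusted p = 0.054), and SULF1 without any one control (0.054 to 0.058) or arterial replicate 1 (0.059). In total 993 genes rose and 723 fell, 1716 of 22574, and 908 of these changed at least 2-fold. Without arterial replicate 1 the count was 1266. It fell further without control replicate 1 (522), 2 (980) or 3 (626) and without arterial replicate 2 (995) or 3 (1094). The share of calls that rose was 57.9%. It was 47.5% with DESeq2, where 1422 genes rose and 1573 fell, and 47.1% with limma on the deposited normalized values (886 and 995), which moved the median of all genes to -0.183 from -0.07, and at most 67.4%, without control replicate 2.

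Arterial marker genes did not rise with the arterial combination: of 18 tested, 0 rose and 6 fell, or 1 and 10 adjusted over the list alone (median -0.65, adjusted p = 2.1e-05). GJA5, a gap junction protein of arteries, changed by -2.69 ± 0.5 to 9.07 ± 5.18 from 63.4 ± 6.37 CPM. GJA4 changed by -2.01, and EFNB2, the ephrin that marks arteries, by -1.30. Venous markers also fell, 5 of 17 with 0 rising, or 8 and 0 adjusted over the list alone (median -0.83, adjusted p = 2.6e-06), with IL1R1 at -1.97 and PLVAP at -1.63. Of 12 Notch pathway genes 4 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -1.02, adjusted p = 2.6e-06), among them the ligand JAG1 at -1.21. With an estimated correlation these 3 calls were lost, at an adjusted p of 0.19 for arterial markers, 0.18 for venous markers and 0.19 for Notch genes.

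The p53 target genes rose, 5 of 15 with 0 falling, or 6 and 0 adjusted over the list alone (median 0.45, adjusted p = 2e-05, adjusted p = 0.1 with an estimated correlation). GDF15, a stress-induced cytokine, rose by 1.70 ± 0.21 to 108 ± 3.97 from 35.6 ± 3.91 CPM, and the cell cycle inhibitor CDKN1A by 1.01 ± 0.18. Of 14 epithelial genes 2 rose, KRT7 by 3.27 ± 0.59 and KRT19 by 1.70, or 3 adjusted over the list alone, and 0 fell (adjusted p = 0.0068, adjusted p = 0.19 with an estimated correlation). Of 19 interferon response genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p = 4.4e-05, adjusted p = 0.52 with an estimated correlation). These were OASL (4.91 ± 1.14) and MX2 (4.44 ± 1.01), antiviral genes whose SDs exceeded their means in the arterial group. Both calls were lost without arterial replicate 2 (0.065 and 0.069) or control replicate 1 (0.13 and 0.09) or 3 (0.11 and 0.089), and OASL also without control replicate 2 (0.084). Stress response genes rose, 2 of 11 with 0 falling, or 4 and 1 adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.19 with an estimated correlation). These were CHAC1 (1.60) and PPP1R15A (0.94). PPP1R15A was lost without control replicate 1 (0.082), and CHAC1 without any one control (0.095 to 0.15) or arterial replicate 1 (0.12) or 3 (0.051). The cell cycle list passed as higher although 0 of its 23 genes did (adjusted p = 0.0036, adjusted p = 0.59 with an estimated correlation).

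The other 16 tested lists did not pass, with adjusted p between 0.051 and 0.99. Among pan-endothelial genes 2 of 23 rose, EGFL7 by 1.20 among them, and 4 fell, including CD34 at -2.52 and TEK, the angiopoietin receptor, at -1.11 (adjusted p = 0.051). Of 19 mesenchymal genes 1 rose and 4 fell, and of 14 tip cell genes 3 rose and 2 fell, with ANGPT2 at 1.53 and the basement membrane collagen COL4A1 at -1.25. Inflammatory genes had 4 of 15 rising, or 6 with 6 falling adjusted over the list alone, and included CXCL1 at 1.68 and IL1A at 1.71. The water channel AQP1 changed by -6.23 ± 1.03 on the flow response list, where 1 of 10 rose and 3 fell. Counts rising and falling were 2 and 1 of 13 capillary markers, 1 and 1 of 21 blood-brain barrier genes, 0 and 1 of 16 junction genes, 0 and 1 of 5 lymphatic genes, and 0 and 0 of 6 pluripotency genes. They were 2 and 0 of 9 Wnt targets, 1 and 1 of 12 PPARD and fatty acid oxidation genes, 3 and 2 of 11 TGF-beta targets, 0 and 1 of 9 BMP targets, 2 and 0 of 17 hypoxia and glycolysis genes, and 0 and 2 of 15 sterol synthesis genes. The median, the mean and the test differed in sign for the capillary marker, inflammatory, pluripotency, Wnt and tip cell lists.

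What changed with the capillary combination? PI16, a peptidase inhibitor, rose by 12.42 ± 1.18 on the log2 scale to 224 ± 42.8 from 0.0431 ± 0.0746 CPM (n = 3 each, adjusted p = 8.4e-05). KLK10, a secreted serine protease that shear stress induces in endothelium, rose by 10.37 ± 0.7 to 132 ± 19.2 from 0.0969 ± 0.0383 CPM (adjusted p = 4.9e-06). IGFBP5, a binding protein of insulin-like growth factors, rose by 9.20 ± 0.91 to 266 ± 23.7 CPM. The other highest were MFAP5 (8.15), CRABP2 (8.07 ± 0.6), CCN3 (7.98), NTS (7.10), the precursor of neurotensin, and PTHLH (7.03). NPR3 fell 67.3-fold to 2.29 ± 1.62 CPM (adjusted p = 0.00017), and FABP4, a fatty acid carrier of capillary endothelium, fell 13.5-fold to 10.6 ± 2.09 from 147 ± 43 CPM (adjusted p = 1.4e-06).

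The other lowest genes were PLCE1-AS1 (-5.03), GPC5 (-4.10 ± 0.43), GJA5 (-3.87 ± 0.52), CCDC3 (-3.68), TSPAN7 (-3.62) and A2M (-3.61). In total 897 genes rose and 674 fell, 1571 of 22574, and 1044 of them changed at least 2-fold. All 16 genes named by rank kept their call when any single library was left out. The count fell to 845, 1021 and 851 without control replicate 1, 2 or 3 and to 997 without capillary replicate 3.

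Of the 10 tested KLF2 and flow response genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (median 1.88, adjusted p = 5.6e-12). This call held with an estimated correlation (adjusted p = 0.0047). THBD, an anticoagulant receptor for thrombin, rose by 3.92 ± 0.3 to 341 ± 80.9 from 23.3 ± 4.86 CPM (adjusted p = 5.8e-06). SLCO2A1 rose by 4.42 ± 0.69 to 67 ± 17.9 from 3.25 ± 1.74 CPM (adjusted p = 0.002). NOS3, the endothelial nitric oxide synthase, rose by 2.31 ± 0.28 to 39.8 ± 8.41 from 8.3 ± 1.24 CPM. AQP1, at 7.88 ± 2.51 against 15.3 ± 5.21 CPM, was not called (-0.90, adjusted p = 0.67). CYP1B1 rose by 7.02 ± 1.27 and ASS1, which supplies arginine for nitric oxide, by 4.73 ± 0.96. CYP1B1 was lost without control replicate 2 (adjusted p = 0.059), and ASS1 without control replicate 2 (0.07) or 3 (0.062).

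**Figure D3:**
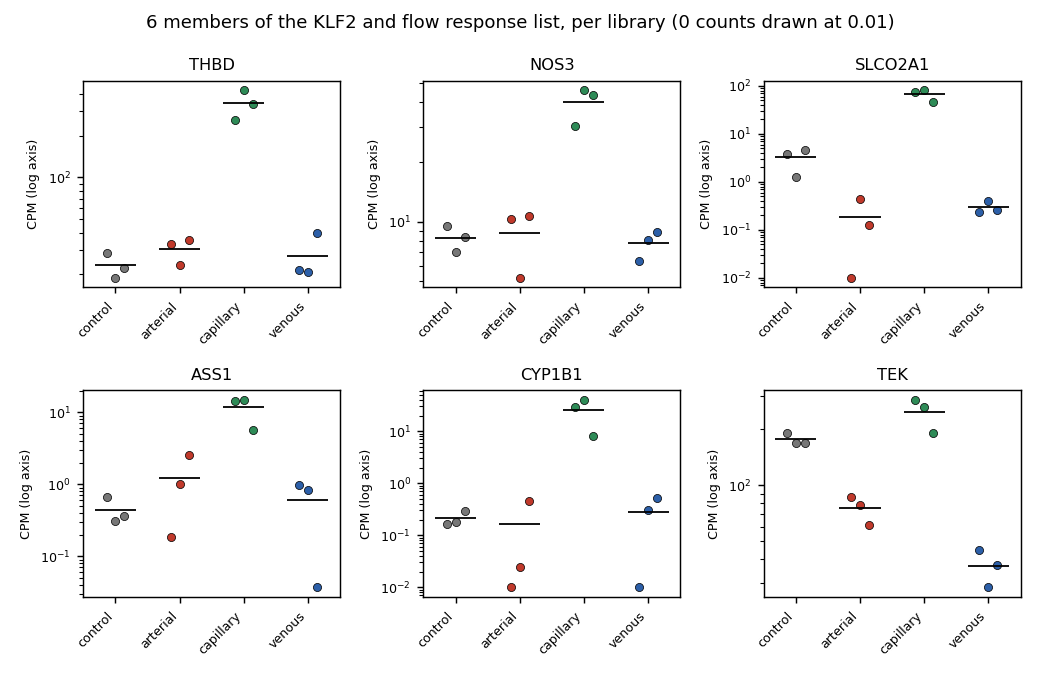
Levels of 6 members of the KLF2 and flow response list in the 12 iEC libraries, in CPM on log axes with 0 counts drawn at 0.01. Points are libraries by group and lines are group means. THBD rose to 341 ± 80.9 CPM in the capillary combination from 23.3 ± 4.86 in control.

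Capillary markers as a list did not pass: 0 of 13 rose and 1 fell, BTNL9 at -3.94 (adjusted p = 0.82 for the list). BTNL9 was lost without control replicate 1 (0.13) or 3 (0.074) or any one capillary library (0.052 to 0.11). Arterial markers fell, 7 of 18 with 0 rising, and the same adjusted over the list alone (median -0.69, adjusted p = 5.1e-11), including BMX (-2.67), DLL4 (-1.88) and EFNB2 (-1.86). Of 12 Notch pathway genes 6 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -1.10, adjusted p = 5.6e-12). Of 17 venous markers 8 fell and 1 rose, or 10 and 1 adjusted over the list alone (median -0.73, adjusted p = 7.2e-06). IL1R1 fell by 2.40 on the log2 scale, and APLNR, the apelin receptor, rose by 2.59 ± 0.27 to 18.2 ± 1.73 from 3.1 ± 0.605 CPM. These 3 calls were lost with an estimated correlation, at an adjusted p of 0.053, 0.053 and 0.11.

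Mesenchymal genes fell, 5 of 19 with 2 rising, or 8 and 3 adjusted over the list alone (adjusted p = 0.00064, adjusted p = 0.16 with an estimated correlation). Fibronectin, FN1, changed by -2.15 to 277 ± 61.2 from 1260 ± 46.9 CPM, and the calcium-binding S100A4 by 3.73 ± 0.59. Of 19 interferon response genes 3 rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 3.5e-09, adjusted p = 0.27 with an estimated correlation). MX2 rose by 6.45 ± 1.08 to 7.58 ± 5.28 CPM, OASL by 4.48 and OAS1 by 2.91 ± 0.68. OASL was lost without any single library (0.064 to 0.17), and OAS1 without control replicate 1 (0.11) or 2 (0.14) or any one capillary library (0.056 to 0.072). The p53 targets rose, 4 of 15 with 0 falling, or 8 and 0 adjusted over the list alone (median 0.50, adjusted p = 7.2e-06), and this held with an estimated correlation (adjusted p = 0.048). GDF15 rose by 1.63, CDKN1A by 1.0 and MDM2, which degrades p53, by 0.87. Stress response genes rose, 2 of 11 with 0 falling, or 3 and 0 adjusted over the list alone (adjusted p = 0.025, adjusted p = 0.16 with an estimated correlation). Of 15 sterol synthesis genes 2 fell and 0 rose, or 4 and 0 adjusted over the list alone (adjusted p = 0.00064, adjusted p = 0.25 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -1.61.

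The other 15 lists had adjusted p between 0.05, which for epithelial genes lay just over the threshold, and 0.87. Pan-endothelial genes went both ways, with 4 rising, including EGFL7 at 1.46, and 4 falling, including VWF at -1.34 and CLEC14A at -1.76. CLDN5, the main claudin of endothelial tight junctions, fell by 1.20 on the log2 scale to 96.7 ± 30 from 227 ± 30.8 CPM. CXCL8 (3.18) and IL1A (2.93) rose and CXCL2 (-2.41) fell among inflammatory genes, 3 and 3 of 15. BMPER fell by 3.02 and ID1 rose by 1.14 among BMP targets. Counts rising and falling were 1 and 1 of blood-brain barrier, epithelial and PPARD genes, 2 and 1 of pluripotency and BMP genes, 1 and 2 of lymphatic genes and 2 and 2 of junction genes. They were 0 and 0 of cell cycle genes, 2 and 0 of Wnt targets, 1 and 3 of TGF-beta targets, 4 and 3 of tip cell genes, and 1 and 0 of hypoxia genes. The median, the mean and the test differed in sign for the capillary marker, blood-brain barrier, junction and BMP lists.

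What changed with the venous combination? The largest fold changes among the named genes were losses. NPR3 fell 109-fold to 1.38 ± 0.523 CPM, and ENPP2, the enzyme that makes lysophosphatidic acid, fell 71.7-fold to 1.15 ± 0.162 from 90.2 ± 14.4 CPM (n = 3 each, adjusted p = 6.2e-07). COL1A2, a chain of type I collagen, changed by -5.16 ± 0.67 to 2.26 ± 1.37 from 86.8 ± 30 CPM. TNFSF18 rose by 3.80 ± 0.65 to 103 ± 30.2 from 7.86 ± 6.04 CPM (adjusted p = 0.0025). G0S2, an inhibitor of lipid breakdown, rose by 3.45 ± 0.7 to 124 ± 44.6 from 12.2 ± 10.9 CPM (adjusted p = 0.0065).

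The other highest genes were SERPINB2 (3.56 ± 0.43), LINC01235 (3.49), FAM24B (3.37), KCNAB1 (3.32 ± 0.44), CST1 (3.30) and PTPN22 (3.29), and the other lowest were COL3A1 (-6.53 ± 1.32), PLCE1-AS1 (-6.33), TSPAN7 (-5.42), SULF1 (-5.27) and A2M (-5.02). FAM24B was lost without control replicate 1 (adjusted p = 0.058) or venous replicate 2 (0.063) or 3 (0.057), and COL3A1 without venous replicate 1 (0.052). In total 1651 genes rose and 1584 fell, 3235 of 22574, and 1818 changed at least 2-fold. The count was 1943 without control replicate 1, 1938 without control replicate 3 and 1994 without venous replicate 2.

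Venous markers fell with the venous combination, 11 of 17 with 1 rising, or 15 and 1 adjusted over the list alone (adjusted p = 3.6e-14). VCAM1 changed by -5.14, LRG1 by -4.25, and SELP, the adhesion receptor P-selectin, by -4.08 to 3.3 ± 2.48 from 59.3 ± 8.68 CPM. Arterial markers fell, 12 of 18 with 0 rising, and the same adjusted over the list alone (median -1.26, adjusted p = 2.3e-13), with GJA5 at -4.99 ± 0.56, GJA4 at -3.09 and BMX at -2.62. Notch pathway genes fell, 7 of 12 with 0 rising, or 8 and 0 adjusted over the list alone (median -1.47, adjusted p = 2.4e-12), including HES4 at -2.49 and EFNB2 at -2.22. Mesenchymal genes fell, 9 of 19 with 1 rising, or 12 and 3 adjusted over the list alone (median -2.48, adjusted p = 5.4e-09). These 4 calls held with an estimated correlation (adjusted p = 0.028 each).

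Calls for 9 further lists were lost with an estimated correlation. Pan-endothelial genes fell, 6 of 23 with 3 rising, or 8 and 3 adjusted over the list alone (adjusted p = 0.0021, adjusted p = 0.24 with an estimated correlation), with VWF at -2.97, CD34 at -2.48 and TEK at -2.14. The lymphatic list fell, 3 of 5 with 0 rising, and the same adjusted over the list alone (adjusted p = 0.00085, adjusted p = 0.096 with an estimated correlation), with the receptor FLT4 at -2.28. Inflammatory genes fell, 7 of 15 with 3 rising, or 9 and 5 adjusted over the list alone (adjusted p = 0.026, adjusted p = 0.36 with an estimated correlation), including CXCL2 at -3.80 and CCL2 at -2.56, to 208 ± 61.2 from 1350 ± 198 CPM. Flow response genes fell, 3 of 10 with 0 rising, and the same adjusted over the list alone (adjusted p = 0.033, adjusted p = 0.2 with an estimated correlation), with AQP1 at -7.25 ± 1.12. BMP targets fell, 3 of 9 with 1 rising, and the same adjusted over the list alone (adjusted p = 0.033, adjusted p = 0.24 with an estimated correlation), with BMPER at -4.28. Sterol synthesis genes fell, 7 of 15 with 0 rising, and the same adjusted over the list alone (adjusted p = 7e-05, adjusted p = 0.17 with an estimated correlation). HMGCS1 changed by -1.79 to 14.1 ± 2.39 from 53 ± 7.21 CPM.

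Lists that rose were the p53 targets, 7 of 15 with 0 falling, and the same adjusted over the list alone (adjusted p = 5e-04, adjusted p = 0.063 with an estimated correlation), and the cell cycle genes. Of 23 cell cycle genes 4 rose and 0 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.00084, adjusted p = 0.43 with an estimated correlation). BIRC5, which acts in chromosome segregation, rose by 1.01 (adjusted p = 0.0055), and PLK1 by 1.24, CCNB1 by 0.96 and TPX2 by 0.80. Without venous replicate 2 the last 3 were lost, at adjusted p values of 0.12, 0.2 and 0.12. They were also lost without control replicate 1 (0.11, 0.13 and 0.058) or 3 (0.066, 0.12 and 0.074), PLK1 and CCNB1 without venous replicate 1 (both 0.084), and PLK1 without control replicate 2 (0.059). Epithelial genes rose, 3 of 14 with 1 falling, and the same adjusted over the list alone (adjusted p = 0.037, adjusted p = 0.24 with an estimated correlation), with KRT19 at 1.94 and SPINT2 at -3.08. Without arterial replicate 1 in the fit the epithelial list had an adjusted p of 0.085.

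The other 11 lists had adjusted p between 0.18 and 0.86. PPARD and fatty acid oxidation genes had 2 rising and 1 falling of 12 (adjusted p = 0.63). PDK4, a PPARD target that restrains glucose oxidation, changed by -2.85 to 2.94 ± 1.34 from 22.9 ± 5.33 CPM, and UCP2 rose by 2.19. Tip cell genes had 4 rising, including PGF at 3.23 and APLN at 2.11, and 5 falling, including COL4A1 at -1.99. Counts rising and falling were 2 and 1 of capillary markers, 1 and 3 of blood-brain barrier genes, 1 and 1 of pluripotency genes, 0 and 4 of junction genes with TJP1 at -1.75, and 0 and 1 of interferon genes. They were 3 and 1 of stress response genes, 2 and 1 of Wnt targets, 3 and 3 of TGF-beta targets, and 4 and 2 of hypoxia genes with the glycolytic ENO1 at 1.45. The median, the mean and the test differed in sign for the capillary marker, interferon, Wnt and PPARD lists.

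How much of the change was common to the 3 combinations? In all 3, 382 genes rose and 333 fell, 715 in total, which was 41.7% of the arterial, 45.5% of the capillary and 22.1% of the venous calls. Chance with independent calls gives 2.89 and 1.51, but the comparisons share their controls, and part of the excess may come from that. Simulated unchanged groups gave 0 such genes, but with hardly any calls they do not measure this part. With each combination set against a different single control, in all 6 assignments, 14 to 55 genes were called the same way in all 3, where independent calls give at most 0.00637. These fits take a lone control to vary like the other groups, and they were chosen after the overlap had been seen. In the mean of the 3 combinations NPR3 fell 52-fold to 3.83 ± 3.97 CPM (n = 9, -5.70 ± 0.41, adjusted p = 8.2e-06), ENPP2 fell 16.6-fold (adjusted p = 1.2e-07) and GJA5 changed by -3.85 ± 0.35 (adjusted p = 1.4e-05). CCN3, a matricellular protein, rose 27.1-fold (4.76 ± 0.43), SERPINB2 by 4.0 ± 0.41 to 69.5 ± 28.1 CPM (adjusted p = 3.7e-05) and IL1RL1 by 3.40 ± 0.34 to 2480 ± 936 CPM. The other named genes were ANOS1 and TNFSF18 (both 3.30), PLCE1-AS1 (-5.10) and TSPAN7 (-3.90), and all 10 kept their call when any single library was left out.

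Against control 1637 genes rose and 1700 fell in the mean of the 3 combinations, 3337 of 22574, with 1501 changed at least 2-fold. The count was 1510, 2073 and 1618 without control replicate 1, 2 or 3. Of the 24 lists tested 11 passed, and 4 held with an estimated correlation (adjusted p = 0.033 each). These were arterial markers with 9 of 18 falling, venous markers with 10 of 17, Notch genes with 8 of 12, and p53 targets with 6 of 15 rising. No member of the 4 went the other way, and adjusted over the list alone the counts were 11, 12, 10 and 6. VWF changed by -2.45 ± 0.2, SELP by -2.87, GDF15 by 1.52 and CDKN1A by 1.04.

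Mesenchymal genes fell, 9 of 19 with 1 rising, or 12 and 3 adjusted over the list alone (adjusted p = 2e-06, adjusted p = 0.077 with an estimated correlation), with COL1A1 at -3.02. Sterol synthesis genes fell, 6 of 15 with 0 rising, or 7 and 0 adjusted over the list alone (adjusted p = 0.0024, adjusted p = 0.28 with an estimated correlation), with HMGCS1 at -1.51. The lymphatic list fell with 2 of 5 members, and the same adjusted over the list alone (adjusted p = 0.0046, adjusted p = 0.17 with an estimated correlation). Epithelial genes (3 rising, 1 falling, or 4 and 1 adjusted over the list alone), interferon genes (2 and 0, or 2 and 0), stress response genes (3 and 1, or 3 and 1) and cell cycle genes (1 and 0, or 0 and 0) passed as higher, with adjusted p values of 0.019, 0.0024, 0.036 and 0.014. With an estimated correlation these had an adjusted p of 0.23, 0.57, 0.21 and 0.58. Without arterial replicate 1 the epithelial list had an adjusted p of 0.053, and the stress response list one of 0.05, just over the threshold. None of these 7 lists passed in each combination. The mesenchymal and sterol lists did not in the arterial one, the epithelial and cell cycle lists in the capillary one or the interferon and stress response lists in the venous one, and the lymphatic list passed in the venous one alone. The other 13 lists had adjusted p between 0.051 and 0.96, and the capillary marker, pluripotency, inflammatory and Wnt lists differed in sign between median, mean and test. FOXP1 fell in the mean of the 3 combinations (-1.0, adjusted p = 5.4e-05). KLF2 (1.74), PPARD (1.46), FLI1 (-0.73) and HEY1 (-0.59) passed too, but not in each combination. PPARD was called in the venous combination alone (0.12 and 0.44 in the arterial and capillary ones), HEY1 and KLF2 were not called in the arterial one, and FLI1 was not in the capillary one. KLF2 and PPARD were lost without any one control (0.058 to 0.12), and FLI1 without control replicate 1 (0.11) or 3 (0.063). HEY1 was lost without any one control (0.092 to 0.24), arterial replicate 2 (0.054) or 3 (0.09), capillary replicate 2 (0.076) or 3 (0.091), or venous replicate 2 (0.071).

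**Figure D4:**
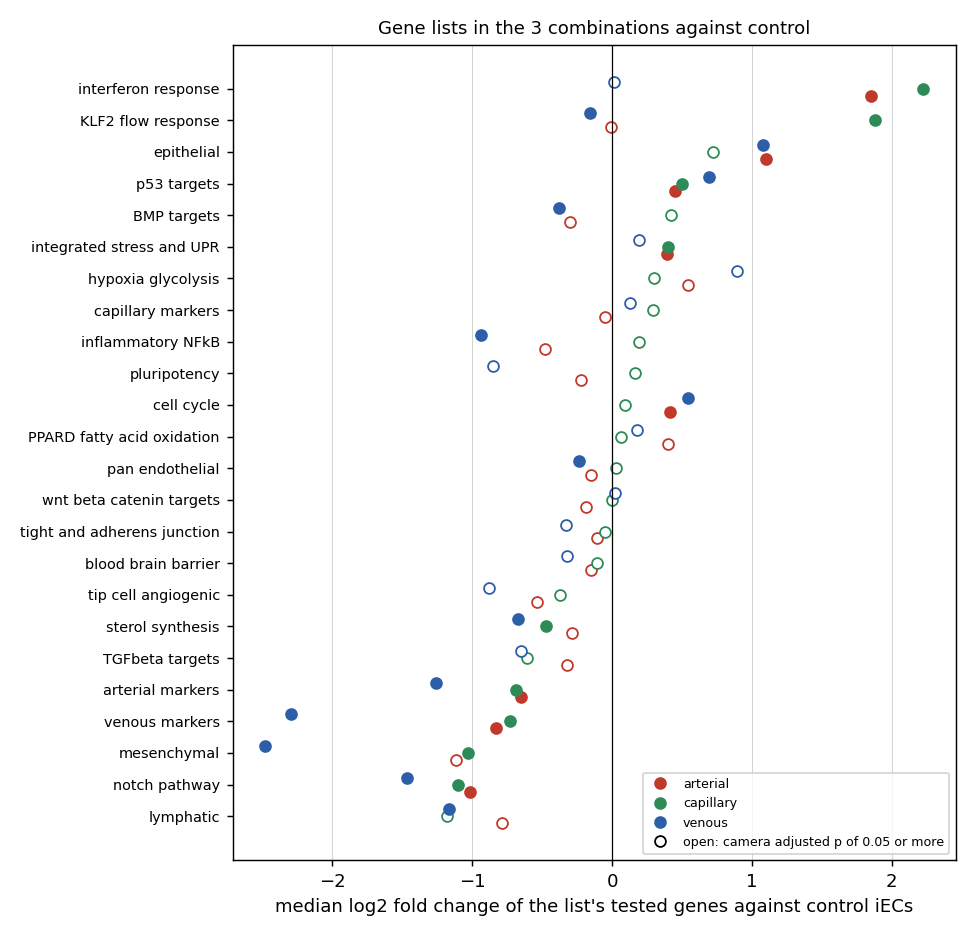
Median log2 fold change of each gene list against control for the arterial, capillary and venous combinations, over the tested genes of the list. Filled points passed camera at an adjusted p under 0.05 and open points did not. Flow response genes lay at 1.88 in the capillary combination. Medians of the interferon, venous marker and epithelial lists include fitted values of genes near 0 counts.

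Between pairs of combinations, 778 genes changed the same way in the arterial and capillary ones, 1414 in the arterial and venous ones and 1034 in the capillary and venous ones. The log2 fold changes of these pairs correlated across genes at r = 0.499, 0.604 and 0.582, where simulated unchanged groups that share their controls had means of 0.509, 0.497 and 0.504. The correlation of the arterial and capillary responses was thus no higher than in the simulations. The covariances were 0.896, 1.1 and 1.02 against simulated means of 0.451, 0.446 and 0.447. With a different control for each combination r was 0.247 to 0.343 over the pairs and assignments. Genes are not independent replicates. Only 5, 2 and 15 were called in opposite directions, 17 genes in all. Each passed a direct test too, which this choice nearly ensures. HEG1, a receptor that stabilizes endothelial junctions, rose by 1.99 ± 0.21 in the capillary combination (adjusted p = 6.4e-05) and fell by 1.12 ± 0.21 in the venous one (adjusted p = 0.0024, direct test 8.9e-06). This gene was chosen after its values were seen.

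How did the capillary combination differ from the venous one? KLK10 had 132 ± 19.2 CPM in the capillary and 0.00237 CPM in the venous libraries, a ratio of 35500 with a counting interval of 6370 to 1400000 (n = 3 each, adjusted p = 8.9e-06). PI16 was higher by 11.51 ± 1.12 on the log2 scale, MFAP5 by 11.02 and IGFBP5 by 9.32 ± 0.92. FABP4 was 8.3-fold lower (adjusted p = 8.9e-06), at 10.6 ± 2.09 against 83.3 ± 10.6 CPM, and SNTG1 changed by -2.02 ± 0.24. ADTRP (-2.47, adjusted p = 0.013), LINC01235 (-2.19, adjusted p = 0.024) and PTPN22 (-1.99, adjusted p = 0.03) were the other lowest. Each was lost without capillary replicate 1 (0.056, 0.087 and 0.096) or 2 (0.052, 0.1 and 0.13) or venous replicate 2 (0.076, 0.12 and 0.14), and PTPN22 also without capillary replicate 3 (0.058) or venous replicate 1 (0.076). LEF1 was higher by 7.41 (adjusted p = 0.0046, or 0.056 without venous replicate 3), PPARD was lower by 3.40 (adjusted p = 0.0017), and KLF2 did not differ (0.04, adjusted p = 0.99).

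Of 10 flow response genes 8 were higher in the capillary combination and 0 lower, or 9 and 0 adjusted over the list alone (median 3.11, adjusted p = 2.3e-29, adjusted p = 0.00027 with an estimated correlation). SLCO2A1 was 204-fold higher, at 67 ± 17.9 against 0.299 ± 0.0861 CPM (adjusted p = 0.00038), and AQP1 was higher by 6.35 (7.88 ± 2.51 against 0.113 ± 0.133 CPM). Pan-endothelial genes were higher, 5 of 23 with 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 4.2e-06, adjusted p = 0.13 with an estimated correlation). Among them CD34 was at 172 ± 50.6 against 17 ± 2.86 CPM (3.27 ± 0.25), TEK was higher by 2.66 and NOS3 by 2.28. Venous markers were higher in the capillary than in the venous combination, 5 of 17 with 0 lower, or 10 and 1 adjusted over the list alone (adjusted p = 2.8e-08, adjusted p = 0.1 with an estimated correlation), with APLNR at 3.23.

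Interferon response genes were higher in the capillary combination, 4 of 19 with 0 lower, or 16 and 0 adjusted over the list alone (adjusted p = 2e-14, adjusted p = 0.19 with an estimated correlation). Among them MX2 was higher by 8.55 ± 1.25 (adjusted p = 0.0018). Inflammatory genes (5 higher, 1 lower, or 9 and 1 adjusted over the list alone, adjusted p = 5.2e-07), mesenchymal genes (5 and 1, or 6 and 1, adjusted p = 9.3e-06) and BMP targets (2 and 0, or 4 and 0, adjusted p = 0.0019) were higher, and so were arterial markers with 1 of 18 members (adjusted p = 0.014). The cell cycle list was lower with 1 member, BIRC5, or 2 adjusted over the list alone (adjusted p = 5.5e-06). BIRC5 changed by -0.87 (adjusted p = 0.04), and was lost without capillary replicate 2 (0.21) or 3 (0.097) or venous replicate 1 (0.059) or 2 (0.22). With an estimated correlation these 5 lists had an adjusted p of 0.13, 0.1, 0.13, 0.38 and 0.4. The other 15 lists had adjusted p between 0.098 and 0.98, with differing signs of median, mean and test for the epithelial, Wnt, TGF-beta, tip cell and hypoxia lists. In total 500 genes were higher and 191 lower, 691 of 22574, with 478 at least 2-fold, and the count was 380 and 252 without capillary replicate 1 or 2 and 282 without venous replicate 2. The share that was higher, 72.4%, became 84.5% with only the libraries compared in the fit (393 and 72).

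How did the arterial combination differ from the capillary one? FABP4 was 8.91-fold higher in the arterial combination, at 90 ± 9.24 against 10.6 ± 2.09 CPM (n = 3 each, adjusted p = 1.1e-05). CLDN10, a tight junction claudin, was higher by 2.73 ± 0.31 (adjusted p = 0.00032) and PDE3A by 2.10. KRT7 (2.58 ± 0.57, adjusted p = 0.039) and the fatty acid receptor CD36 (2.46 ± 0.48, adjusted p = 0.017) were also higher. KRT7 was lost without any one arterial library (0.087 to 0.1) or capillary replicate 1 (0.12) or 2 (0.11). CD36 was lost without any one capillary library (0.06 to 0.1) or arterial replicate 1 (0.069) or 2 (0.063). SLCO2A1 was 340-fold lower at 0.188 CPM (adjusted p = 0.00034), and MFAP5 (-10.13 ± 1.1), IGFBP5 (-9.60 ± 0.93), KLK10 (-9.37 ± 0.66) and PI16 (-8.43 ± 0.93) were lower. HEY1 was higher by 1.11 ± 0.23 (adjusted p = 0.024), PRDM16 higher by 7.68 (adjusted p = 0.0097) and LEF1 lower by 4.28 ± 0.96 (adjusted p = 0.048). Without arterial replicate 2 these had an adjusted p of 0.077, 0.052 and 0.14, and without capillary replicate 2 of 0.12, 0.07 and 0.15. HEY1 was also lost without arterial replicate 1 (0.093) or capillary replicate 3 (0.078), and LEF1 without arterial replicate 3 (0.091) or capillary replicate 1 (0.13) or 3 (0.11).

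Flow response genes were lower in the arterial combination, 7 of 10 with 0 higher, or 8 and 0 adjusted over the list alone (median -2.65, adjusted p = 1.2e-20, adjusted p = 0.001 with an estimated correlation). THBD was at 30.6 ± 6.24 against 341 ± 80.9 CPM (-3.42 ± 0.29, adjusted p = 2.5e-05). Pan-endothelial genes were lower as a list, with 4 of 23 lower and 2 higher, and the same adjusted over the list alone (adjusted p = 0.0081, adjusted p = 0.69 with an estimated correlation). The lower ones included CD34, at 16.6 ± 2.98 against 172 ± 50.6 CPM (-3.31 ± 0.25), NOS3 (-2.14) and VWF (-1.69). Arterial markers were higher than in the capillary combination, 2 of 18 with 0 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.012, adjusted p = 0.69 with an estimated correlation), among them the tyrosine kinase BMX at 1.57. Notch, cell cycle and sterol synthesis genes passed as higher lists although no member did, with adjusted p values of 0.02, 0.0012 and 0.012. Adjusted over the list alone 2 Notch genes and 0 of the other two lists were higher, and the estimated correlation gave an adjusted p of 0.69, 0.78 and 0.69. Without arterial replicate 1 the sterol list had an adjusted p of 0.091.

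The other 18 lists had adjusted p between 0.053 and 0.99. The median, the mean and the test differed in sign for 9 of them, the venous, capillary, blood-brain barrier, epithelial, lymphatic, mesenchymal, stress response, TGF-beta and hypoxia lists. In total 137 genes were higher and 281 lower in the arterial combination, 418 of 22574, with 341 at least 2-fold. The count was 252 and 242 without arterial replicate 1 or 2, and 250 and 179 without capillary replicate 1 or 2. The share that was higher, 32.8%, became 22.3% with only the libraries compared in the fit.

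How did the arterial combination differ from the venous one? ADAMTS1, a protease that restrains angiogenesis, was 11.6-fold higher, at 19.7 ± 9.4 against 1.69 ± 0.258 CPM (n = 3 each, adjusted p = 0.0017). ENPP2 was higher by 3.48 ± 0.3, at 12.9 ± 2.18 against 1.15 ± 0.162 CPM (adjusted p = 0.00028), and DSP, a desmosome protein, by 2.89 ± 0.4 (adjusted p = 0.0087). CRABP2 was higher by 2.87 (adjusted p = 0.025) and TSPAN7 by 2.76 (adjusted p = 0.034). CRABP2 was lost without any one venous library (0.085 to 0.18), and TSPAN7 without any one venous library (0.092 to 0.26) or arterial replicate 1 (0.11) or 2 (0.14). PPARD was lower by 3.72 ± 0.51 (adjusted p = 0.0077), and PRDM16 was higher by 7.29 ± 1.38 (adjusted p = 0.039). PRDM16 was lost without arterial replicate 2 (0.19) or venous replicate 1 (0.051), 2 (0.24) or 3 (0.088), and HEY1 was not called (0.90, adjusted p = 0.14). In total 87 genes were higher and 2 lower, 89 of 22574, with 83 at least 2-fold, and no gene met the rule for the lowest. With only these libraries in the fit 6 were called, ADAMTS1 and ENPP2 among them, and DSP, CRABP2, TSPAN7, PPARD and PRDM16 were lost (0.062 to 0.19). The count was 44, 35 and 250 without arterial replicate 1, 2 or 3, and 54 and 9 without venous replicate 1 or 2. The share that was higher, 97.8%, was 83.7% with DESeq2 (343 and 67) and 81% with a filter of at least 1 count (537 and 126).

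As groups, 13 of the 24 lists were higher in the arterial than in the venous combination and 0 lower. Mesenchymal genes were higher, 3 of 19 with 0 lower, or 8 and 0 adjusted over the list alone (adjusted p = 1.6e-14), and this held with an estimated correlation (adjusted p = 0.017). THY1, a surface protein of stromal cells, was higher by 2.51 (adjusted p = 0.0072, or 0.059 without venous replicate 2). Arterial markers were higher, 2 of 18, or 7 adjusted over the list alone (adjusted p = 3.8e-10), and so were venous markers, 2 of 17, or 10 with 1 lower adjusted over the list alone (adjusted p = 5.2e-10). With an estimated correlation both had an adjusted p of 0.069. Inflammatory genes (1 of 15, or 11 adjusted over the list alone, adjusted p = 5.2e-10) and interferon genes (1 of 19, or 7, adjusted p = 1.4e-11) were higher. So were Notch genes (1 of 12, or 5, adjusted p = 2.4e-07) and sterol synthesis genes (0 of 15, or 5, adjusted p = 1.7e-07). With an estimated correlation these 4 had an adjusted p of 0.088, 0.17, 0.096 and 0.093. The list members called were ADGRG6, BMPER, BMX, CXCL2, HES4, ID4, IGFBP3, LYVE1, MX2, PLVAP, SNAI2, TAGLN, TEK and THY1, and none of these 14 kept its call when each library was left out in turn.

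Smaller calls in this comparison were flow response genes (1 higher, or 2 adjusted over the list alone, adjusted p = 0.009), lymphatic genes (1, or 1, adjusted p = 0.01), TGF-beta targets (1, or 2, adjusted p = 0.014), PPARD genes (0, or 0, adjusted p = 0.031), BMP targets (2, or 3 with 1 lower, adjusted p = 0.037) and pan-endothelial genes (1, or 2, adjusted p = 0.037). The estimated correlation gave these an adjusted p of 0.11, 0.16, 0.16, 0.29, 0.22 and 0.36. Without arterial replicate 1 the pan-endothelial list had an adjusted p of 0.095. The other 11 lists had adjusted p between 0.071 and 0.9, and for the p53 targets the test differed in sign from the median and the mean.

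How far apart were iBMECs and control iECs? Most endothelial transcripts tested were far lower in iBMECs, and the epithelial and pluripotency genes tested were higher. PECAM1, the adhesion molecule by which endothelium is recognized, was at 0.109 ± 0.131 CPM in iBMECs (n = 4) and 2080 ± 201 in control (n = 3), a log2 change of -14.60 ± 0.55 (adjusted p = 1.5e-07). CLDN5 was at 0.0206 ± 0.0182 against 227 ± 30.8 CPM (-14.01 ± 0.31, adjusted p = 1.3e-10). CLDN6, a claudin of embryonic epithelia, was at 1350 ± 205 against 0.0165 ± 0.0285 CPM (15.43 ± 0.41, adjusted p = 1.5e-09). RAB25, an epithelial trafficking protein, had 80.3 ± 6.5 CPM in iBMECs and 0 counts in control, at least 6790-fold higher. The RNA-binding protein LIN28A of pluripotent cells was at 128 ± 16.7 CPM, higher by 8.77.

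The other highest genes were WDR86-AS1 (at least 7760-fold), PDPN (at least 5660-fold), VGLL1 (at least 5410-fold), DLX5 (at least 3980-fold) and PRSS8 (at least 3900-fold), all without counts in control. CYP26A1, which degrades retinoic acid, reached 580 ± 82.1 CPM at a ratio of 71400 (19800 to 589000). Lowest were GIMAP4, at 1410 ± 108 CPM in control and a ratio of 350000 (96900 to 2890000), IL33 (-17.92 ± 0.56), LYVE1 (-16.56 ± 0.31) and CLEC14A (-15.33 ± 0.33). PCAT19 (at least 22500-fold lower) and GIMAP7 (at least 3900-fold lower) had 0 counts in iBMECs. In total 7527 genes were higher and 6066 lower, 13593 of 24607, with 9435 at least 2-fold. All 16 genes named by rank kept their call without any single library. The median of all genes was 0.158, and it was 0.686 with a filter of at least 1 count and 0.03 with a stricter filter, so changes of that size carry no direction here.

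All 19 epithelial genes tested were higher (adjusted p = 5.8e-59) and 22 of 23 pan-endothelial genes were lower, or 23 adjusted over the list alone (adjusted p = 6.5e-47). VWF changed by -10.65, KDR, the main receptor of vascular endothelial growth factor, by -9.42, and EMCN, a sialomucin of veins and capillaries, by -13.92 ± 0.14. The exception was NOS3, at 3.67 to 10.1 CPM in the iBMEC libraries (-0.61, adjusted p = 0.073). All 9 pluripotency genes tested were higher (adjusted p = 7.3e-11), with L1TD1 at 12.02 ± 0.24 and SOX2 at least 352-fold higher. The other 2 of the 11 on the list, POU5F1 and PRDM14, had too few counts to be tested. POU5F1 had at most 0.0853 CPM in any library, which need not mean low expression, since the handling of multi-mapping reads was not given. Arterial markers (13 of 18 lower, 2 higher, adjusted p = 5e-09), venous markers (12 of 17 lower, 3 higher, adjusted p = 2.7e-11), inflammatory genes (12 of 13 lower, 0 higher, adjusted p = 2.7e-11) and tip cell genes (11 of 14 lower, 2 higher, adjusted p = 0.00022) were lower. SOX17 changed by -8.93, CXCL8 by -9.71 and ANGPT2 by -8.59. These 7 calls held with an estimated correlation (adjusted p from 0.0087 to 0.049).

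**Figure D5:**
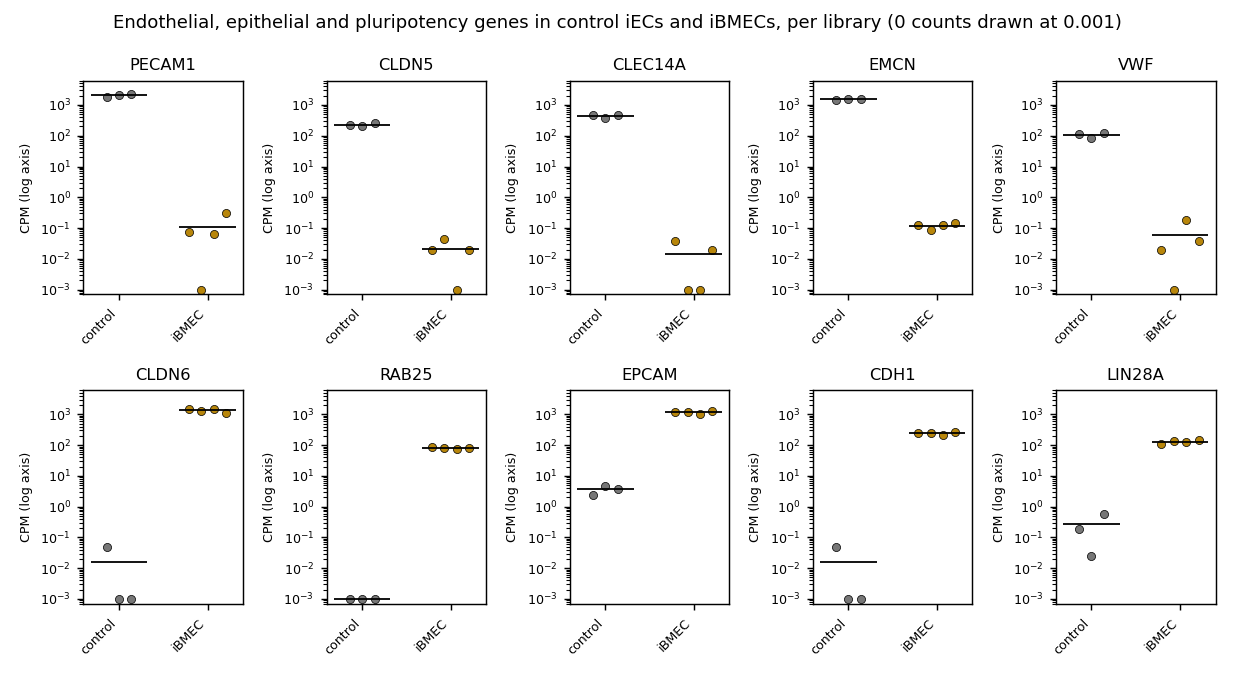
Levels of endothelial genes (top) and of epithelial and pluripotency genes (bottom) in the 3 control and 4 iBMEC libraries, in CPM on log axes with 0 counts drawn at 0.001. Points are libraries and lines are group means. PECAM1 was at 0.109 ± 0.131 CPM in iBMECs and 2080 ± 201 in control.

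Blood-brain barrier genes did not move as a list (11 of 21 higher, 5 lower, adjusted p = 0.42). SLC7A5, which carries large amino acids, was higher by 6.68 at 49.1 ± 7.81 against 0.389 CPM, and the glucose transporter SLC2A1 by 3.05 at 98.8 ± 6.8 against 9.51 ± 0.562 CPM. Junction genes went both ways (6 of 16 higher, 5 lower, adjusted p = 0.45), with the epithelial CGN at 9.19 and the endothelial ESAM at -7.08. Cell cycle genes were higher, 20 of 23 with 1 lower (adjusted p = 6.7e-06, adjusted p = 0.32 with an estimated correlation), including the replication factor MCM2 at 3.46. Mesenchymal genes were higher, 13 of 19 with 1 lower (adjusted p = 0.014, adjusted p = 0.37 with an estimated correlation), with PDGFRB at 2.80. BMP targets were higher, 5 of 9 with 2 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.0037, adjusted p = 0.26 with an estimated correlation). Notch genes (9 of 12 lower, 2 higher, adjusted p = 9e-06), lymphatic genes (3 of 6 lower, 1 higher, adjusted p = 0.0022), interferon genes (11 of 18 lower, or 13 adjusted over the list alone, adjusted p = 0.0022) and flow response genes (5 of 10 lower, or 6 adjusted over the list alone, with 4 higher, adjusted p = 0.01) were lower. With an estimated correlation these 4 had an adjusted p of 0.091, 0.063, 0.43 and 0.26. For the iBMEC lists not given a second count, that adjusted over the list alone was the same.

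The other 10 lists had adjusted p between 0.054 and 0.74. Counts higher and lower were 6 and 5 of 14 capillary markers, 4 and 1 of 7 haematopoietic genes, 2 and 1 of 6 neural genes, 8 and 6 of 15 p53 targets and 7 and 2 of 12 stress response genes. They were 9 and 3 of 12 Wnt targets, with LGR5 at least 113-fold higher, 2 and 8 of 12 PPARD genes, 7 and 3 of 11 TGF-beta targets, 6 and 3 of 17 hypoxia genes and 3 and 8 of 16 sterol synthesis genes. The capillary marker, junction and TGF-beta lists differed in sign between median, mean and test. Of the 9 factors, LEF1 was higher by 3.06 ± 0.59 (adjusted p = 0.0015), and HEY1 (-4.12), KLF2 (-4.48), TSC22D1 (-0.77), FOXP1 (-0.86), FLI1 (-7.54 ± 0.55) and TSHZ2 (-4.04) were lower. PPARD was not called (0.39, adjusted p = 0.26), and PRDM16 had too few counts to be tested.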

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

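The tests of dropout, of mislabelled groups, of the size of the TSHZ2 change, of lost mesenchymal cells and of a different control for each combination were chosen after the results they address had been seen, and so were the form of the pan-endothelial criterion and the minimum of 20 genes named below.

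Arterial replicate 1 lay apart from the other two arterial libraries and carried 7.35 CPM of LEF1, a factor of the capillary combination. Carry-over from capillary libraries was argued against for genes specific to them other than LEF1, since 0 of 11 were above 1 CPM in it. Of the 2 genes that were 4-fold higher in it, 1 lay above every capillary library, a share of 0.5. A share over 0.3 had been set in advance to count against carry-over as the whole difference, but the minimum of 20 genes was set once this share was known, so with 2 genes nothing was decided. A lower number of starting molecules is a candidate explanation, since 0.0191 of 2569 genes at 1 to 5 CPM in the other arterial libraries had 0 counts in it, against at most 0.00156 in any other library, and a biological difference of this sample stays open and untested.

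The 3 combinations shared much of their change against control. Shared control libraries as the whole cause were argued against by fits with a different control for each combination, where the correlation of log2 fold changes stayed at 0.247 or more and at least 14 genes were called the same way in all 3, against at most 0.00637 from independent calls, while 715 genes with shared controls decide nothing. A loss of mesenchymal cells from selected wells would raise endothelial transcripts. It leaves unexplained 5 pan-endothelial genes called lower in the mean (TEK, CLEC14A, VWF, CD34 and EMCN). Whether it lowered mesenchymal genes was not tested. EGFL7 (1.39), ENG (0.84), NOS3 (0.84) and ICAM2 (0.67) rose. Only VWF and CLEC14A fell in each combination, TEK and CD34 were not lower in the capillary one, and NOS3 rose there alone. The count replaced a criterion on the whole list, which was not met (adjusted p = 0.051, median -0.12). All 3 combinations and no control had transduction and puromycin selection. The effect of these and a common effect of the factors cannot be told apart and may each contribute.

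HEY1, TSC22D1, FOXP1, FLI1 and TSHZ2 were not higher than control in the combination that contained them. Mislabelled groups were argued against by PRDM16, LEF1 and PPARD, higher in every library of the labelled combination than in any other iEC library. KLF2 and TSHZ2, also low in control, were not. A transgene signal could be hidden under native transcripts. Rises over the other combinations were compared. The upper 95% limits for TSHZ2 (3.23 CPM), FOXP1 (19.9) and FLI1 (28.5) lay below the interval of LEF1 (40.5 to 68.6). Those of HEY1 (50.4) and TSC22D1 (161) did not. TSHZ2 alone lay below PPARD (13.7 to 20.7), and none below PRDM16 (1.5 to 6.19). Where a limit was not below, a signal of that size stays open. Codon changes or untranslated regions of the viral copies were not given.

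ITGA9, an integrin of lymphatic endothelium, rose with the capillary combination by 2.06 and fell with the venous one by 1.68 on the log2 scale, a difference of 3.74 (adjusted p = 0.00055 in the direct test). Its venous call was lost without control replicate 1 (adjusted p = 0.095) or venous replicate 2 (0.094). ADAMTS1 differed between these responses by 2.56 (adjusted p = 0.0013), rising by 1.21 ± 0.34 in the capillary and changing by -1.35 ± 0.35 in the venous combination. SLCO2A1 differed by 7.67 (adjusted p = 0.00038), rising by 4.42 ± 0.69 and changing by -3.25, a venous call lost without venous replicate 3 (adjusted p = 0.059).

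Single iBMEC libraries lay far from the other 3 in 9 of 115 values, where chance gives about 1 in 20. Scanning began with fewer values and was then widened to all genes named for iBMECs. Replicate 3 had 206.4 M reads, against 90.4 to 106 in the others. Replicate 2 had a mitochondrial share of 6.68% against 6.89% to 6.94%, CXCL10 at 0.122 CPM against 0, and ICAM2 at 0.144 CPM against 0 to 0.0189. Replicate 1 had LUM, a matrix proteoglycan, at 249 CPM against 87.9 to 105, VGLL1 at 84.3 against 56 to 59.4, PRDM16 at 0.123 against 0 to 0.0193, and IL33 at 0.0943 against 0. In replicate 4 the glycolytic regulator PFKFB4 was at 3.1 CPM against 3.85 to 3.86.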

How the results depend on the processing

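The fits of other comparisons without arterial replicate 1 and the replicate block for the overlap were chosen after the data had been seen. Across the alternatives no named gene and no list reversed its direction while called. Of 564 calls of named genes, 562 were kept with DESeq2 (19 gained), 556 with median-of-ratios scaling, 544 with limma on the deposited normalized values, 555 with a filter of at least 1 count (47 gained), 560 without robust estimation, 529 with all 16 libraries in 1 fit and 546 with a replicate block. Kept were 425 of 426 with the stricter filter, 526 of 533 without mitochondrial genes and the factors, and 308 of 365 with only the libraries compared.

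Counts of changed genes moved by more than 1.5 times in these cases. DESeq2 called 2995 genes for the arterial and 2479 for the capillary combination against control, 410 for arterial against venous, 964 for arterial against capillary, 1441 for capillary against venous, and 1194 for the overlap of responses to the combinations. A filter of at least 1 count gave 663, 921 and 1302 genes for arterial against venous, arterial against capillary and capillary against venous. With only the libraries compared, arterial against venous gave 6 genes and arterial against capillary 265, from fits with fewer libraries. The stricter filter gave 8302 genes for iBMECs, from fewer genes tested. Apart from these, the cause was not tested. Of 83 list calls 20 were kept with an estimated correlation. The directional fry test, which asks whether a list moves and not whether it moves more than other genes, called 63 of these and 23 others. The replicate block kept 80 and gained 4, and without arterial replicate 1 the calls kept were 64 of 69, with 2 gained.

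When single libraries were left out, counts ranged from 522 to 1266 for the arterial, from 845 to 1787 for the capillary and from 1938 to 3682 for the venous combination against control, with the highest in each case without arterial replicate 1. They ranged from 9 to 250 for arterial against venous, 179 to 364 for arterial against capillary, 252 to 867 for capillary against venous, 1510 to 3942 for the mean of the 3 combinations and 12262 to 12943 for iBMECs. The overlap of responses to the combinations was 682 without arterial replicate 1 and 920 with a replicate block. The labels do not pair replicates of the same number. Residuals of libraries with the same number correlated across genes at -0.065 to 0.259, over 0.1 in 4 of 18 pairs. A rule that every such pair exceed 0.1 was not met, so none were paired. Pairing remains possible: all 9 same-number pairs of combinations were above 0 (0.013 to 0.259), those of replicates 3 over 0.1. Of 12 libraries 8 correlated best with one of their number, and ribosomal shares rose with it in each combination. Among the splits for the mean of the 3 combinations, the highest other one, with 189 genes, set replicates 1 of the combinations, arterial replicate 1 among them, against the rest, but those of replicates 2 and of replicates 3 gave 0. These are hints from the data, not the design. With a replicate block, BMP targets (adjusted p = 0.05, just over the threshold) and epithelial genes (0.054) in the venous combination and BMP targets for arterial against venous (0.055) were not called. Pan-endothelial genes were, in the arterial combination (0.047) and the mean (0.048), as were PPARD genes in the arterial one (0.047) and interferon genes for arterial against capillary (0.032). With a replicate block the counts were 2213, 1901 and 3798 for the arterial, capillary and venous combinations, 123, 492 and 914 for arterial against venous, arterial against capillary and capillary against venous, 3876 for the mean and 11402 for iBMECs. Read depth of 54 to 206.4 M reads per library limits the values of genes under about 3 counts in a group, which are given as bounds.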

Other observations

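The gene families, 16 in all with some given below, were chosen after the data had been seen, and the splits of the libraries were planned. The GIMAP genes, a cluster of GTPases best known from lymphocytes, fell in every combination. Of 7 tested, 3 fell in the arterial combination (adjusted p = 0.0072, adjusted p = 0.27 with an estimated correlation), 3 in the capillary one (adjusted p = 0.0035, adjusted p = 0.24 with an estimated correlation) and 4 in the venous one (adjusted p = 2.9e-06, adjusted p = 0.035 with an estimated correlation). In iBMECs all 6 tested were lower, but GIMAP genes among the lowest there had prompted the choice of this family. Of 36 collagen genes 14 fell and 2 rose in the mean of the 3 combinations (adjusted p = 2e-05, adjusted p = 0.17 with an estimated correlation). In the venous combination 12 fell and 3 rose (adjusted p = 4.9e-05, adjusted p = 0.17 with an estimated correlation).

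Cytosolic ribosome genes were higher in the venous combination, 9 of 74 with 0 lower (adjusted p = 0.00011, or 0.71 with an estimated correlation). They were lower in the capillary than in the venous combination with 4 members (adjusted p = 2.4e-11, or 0.58 with an estimated correlation). The ribosomal share of counts rose with replicate number in venous (2.92 to 7.39%), arterial (3.15 to 5.17%) and capillary (2.38 to 4.91%) libraries. Controls had 3.96 to 4.20%. Zinc finger genes fell in the mean of the 3 combinations, 56 of 431 with 8 rising (adjusted p = 0.00039, adjusted p = 0.17 with an estimated correlation).

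Set against the other two, the capillary combination was the most distinct, with 577 genes higher and 201 lower, against 118 and 54 for the arterial and 39 and 234 for the venous one. The glycolytic gene LDHA had 0.0494 to 0.521 CPM in every library, whereas PGK1 had 461 to 1120 and GAPDH 918 to 3180. ALDOA, also glycolytic, had 4.0 to 14.4, and IRF7 had at most 0.0221, IRF9 0.0472 and IFI27 0.144. The handling of multi-mapping reads was not given, so such counts need not mean low expression. These values were singled out after they were seen.

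Other splits of the same libraries were refitted. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. The real split gave 1716, 1571 and 3235 genes for the arterial, capillary and venous combinations against control, and the highest other split gave 0, 1 and 0. It gave 89 genes for arterial against venous, 418 for arterial against capillary and 691 for capillary against venous, with 0, 0 and 82 in the highest other split. For the mean of the 3 combinations 1 of 100 splits, the real one, gave as many as 3337 genes and the highest other 189. For iBMECs 1 of 35 splits, the real one, gave as many as 13593 genes and the highest other 0. Chance is thus unlikely in both if libraries are independent.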
